A study of Homo sapiens with 2 samples.

How the data were processed

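RNA of MDA-MB-231 cells, an established human breast cancer cell line, was measured on 2 Affymetrix arrays, 1 per treatment. Per the labels, cells received a miR-544 antagomir or compound 1 for 24 hours before 5 days of hypoxia at below 1% oxygen, RNA was isolated with a Zymo column kit, and biotin-labelled cRNA was made from 5 µg of total RNA. The series design speaks of 3 samples that were pooled before hybridisation; whether this means 3 cultures per treatment is not given in the sources used here. No array of untreated or normoxic cells was used here.

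The deposited table holds 1 value per transcript cluster and array, on a scale that its range (0.61 to 14.19 on the antagomir array and 0.37 to 14.20 on the compound 1 array) places as log2 signal. The log base, the background correction and the normalization behind these deposited log2 values are not given in the sources used here, so each fold below assumes base 2. The array medians were 5.59 and 5.62. The series title names another array type, but the probe numbers and the probe table are those of a gene-level whole-transcript Affymetrix design, on which most genes have 1 cluster. Of 53617 clusters, 16098 had 1 gene symbol in the probe table, 0 had several, and 37519 are unnamed here. All 16098 gene identifiers were found in the RefSeq table for GRCh38.p14, which was used for symbols and gene types only, and 0 symbols needed an update. No column was left unmapped. Identical values on both arrays were held by 1466 clusters, 122 of them chosen for measured genes, and 3151 clusters shared both values with another cluster; the reason is not known.

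No further scaling was applied in the main setting. A cluster entered when its higher value of the 2 arrays reached the 50th percentile of mean levels, a log2 level of 5.60. This left 28058 clusters and 10887 genes, 9584 of them protein-coding. A gene was represented by its entering cluster with the highest mean, and each difference is compound 1 minus antagomir. With 1 array per treatment there is no replicate error and no p-value; differences describe these 2 arrays. For each of 34 gene lists fixed before the data were examined, the median difference was set against 10000 random lists of the same size, matched on mean level in 20 bins, and given as a percentile. A list was marked as outside at a percentile of 2.5 or less or of 97.5 or more, and 4 lists with fewer than 5 measured members got no percentile. Of 859 list entries 454 were measured, for example 13 of 45 oxidative phosphorylation subunits. Each list value thus describes the measured members and not the whole pathway. For simulated lists the differences were shuffled within level bins, and 25 genes were drawn at random from the 10887 genes of this comparison. Of these lists 7 of 100 fell outside with no shift, 63 of 100 with a shift of -0.10, 100 of 100 with -0.20 and 99 of 100 with 0.20, each against 500 random lists. These rates hold for genes that vary independently, and members of a real list may vary together. They also hold for lists of 25 genes spread over all levels. Smaller lists, such as the 5 metallothioneins, and lists at the high level of the mitosis genes were not simulated.

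The rule for named genes fixed before the data were examined asked for at least 2 entering clusters past 2-fold, and 0 genes met it on this array. A replacement was written after the array type was known and before any difference was computed: the 15 highest and 15 lowest protein-coding genes, sex-linked genes left out, besides the 3 members of each list with the largest absolute difference and MTOR. The 6 genes past 2-fold are named as a complete count, and the vault and precursor genes of miR-544 were looked up by name. MKI67, STC2, ANGPTL4, SARS1, ATF3 and KIF4A fall outside this rule and were chosen after their values were seen. HIF1A and ATM are not analysed here. Alternatives were centring, quantile normalization, cyclic loess, 3 other filters, 2 other ways to choose a cluster, other fold thresholds and random lists without level matching. The planned look at array controls, at miR-544a seed matches, at probe set suffixes and at a floor before the logarithm was not run, because the values came on a log scale, cluster numbers carry no suffix and no control names, and no genome was used here. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for cyclic loess. The number of arrays limits the precision.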

Results

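Transcript levels were compared between MDA-MB-231 breast cancer cells given a miR-544 antagomir, an oligonucleotide that blocks this microRNA, and cells given compound 1, which the study directs at the same microRNA. Both were kept in hypoxia for 5 days. Each treatment was represented by 1 array of pooled RNA, so the comparison asks how far the treatments differ in hypoxic cells and holds no untreated reference.

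Named genes differed little between the arrays. Across the 10887 measured genes the levels correlated with r = 0.992 (across genes, which are not independent replicates), and 99.1% of genes lay within 1.5-fold. Protein-coding genes past 2-fold numbered 0, or 3 higher and 3 lower with no filter on level. Among the 16399 entering clusters without a gene name, 57 were higher and 183 lower past 2-fold, and 94.3% lay within 1.5-fold. Of these, 26 of the higher and 112 of the lower came from 1530 clusters numbered below the first named one. In that block 72.9% lay within 1.5-fold. GDF15, a stress-induced secreted cytokine, had the highest difference among measured protein-coding genes, with a log2 level of 8.31 on the antagomir array and 9.12 on the compound 1 array (1.76-fold). EGR1, an immediate early transcription factor, was higher on the compound 1 array by 0.61 and by 0.46 in its separate clusters. The adhesion receptor gene ADGRF1 was lower on that array, at 8.19 against 9.09 (1.86-fold), and so was DDIT4, a hypoxia-inducible inhibitor of mTOR complex 1, at 9.53 against 10.32 (1.73-fold). TIPIN, which encodes a replication fork protein, had a log2 difference of -0.82. The retinal reductase gene DHRS3 and UCN2, a gene of the corticotropin-releasing hormone family, were both at -0.80.

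The other highest protein-coding genes were KRT9, ZNF675, TMEM252, ZNF736, KHDC1L, IL18R1, ACOT4, ARHGEF33, PELI2, STYXL2, CCL18, OTOP1 and DRD3, and 11 of the 15 were under the entry level on the antagomir array. The other lowest were ZNF680, CADPS2, METTL18, ZNF141, DDTL, ZSCAN31, CCDC18, DPY19L2, KL and LCE1C, and 5 of the 15 were under the entry level on the compound 1 array. GDF15, ADGRF1, TIPIN, UCN2, DDIT4, METTL18 and ZNF141 were among the 15 highest or lowest in all 8 alternatives of scaling, filter and cluster choice. Each of these genes has 1 entering cluster, so filter and cluster choice left its value as it was. Centring cannot change a rank. Only quantile normalization and cyclic loess changed these values relative to other genes. With no filter, 10 of the 30 genes were named again.

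**Figure D1:**
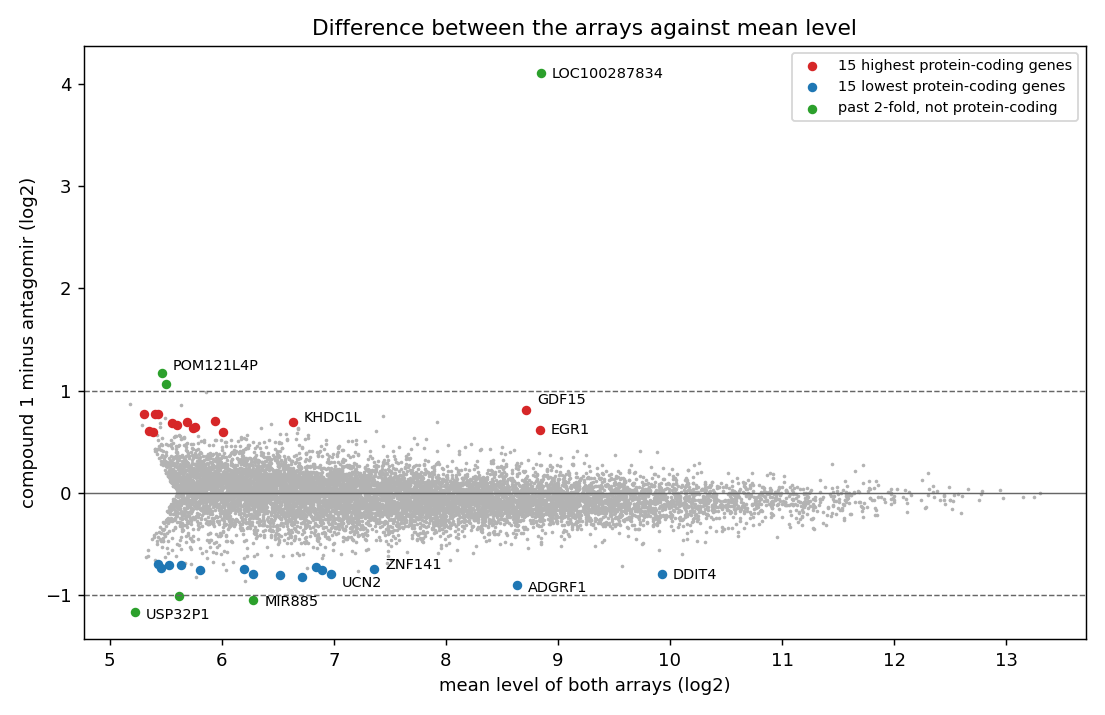
Difference between the arrays (compound 1 minus antagomir, log2) against the mean level of both arrays (log2) for the 10887 measured genes, with 1 point per gene and dashed lines at 2-fold. GDF15 at 0.81 and DDIT4 at -0.79 stand apart at high levels, while most of the 15 highest genes lie at the low end.

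The count past 2-fold depended on the filter, with 29 genes higher and 15 lower with no filter, and 1 and 0 with entry at the 75th percentile of level. In the main setting 3 genes were higher and 3 lower on the compound 1 array (4 and 2 after centring), and none of these 6 codes for a protein. The long non-coding RNA gene LOC100287834 had a level of 10.90 on the compound 1 array and 6.79 on the antagomir array, a 17.3-fold difference. The microRNA gene MIR885 was lower on the compound 1 array, at 5.76 against 6.81 (2.07-fold). The other 4 were under the entry level on one array: the pseudogene POM121L4P (4.88) and the microRNA gene MIR378F (4.97) on the antagomir array, against 6.05 and 6.03 on the compound 1 array, and the pseudogene USP32P1 (4.64) and the microRNA gene MIR501 (5.11) on the compound 1 array, against 5.80 and 6.12. The precursor genes MIR544A and MIR544B were under the entry level on both arrays, at 4.78 and 3.52 on the antagomir array and 4.83 and 3.60 on the compound 1 array. MTOR, the kinase gene at the centre of the pathway that the study addresses, was at 9.05 and 9.06, a difference of 0.009. After quantile normalization this difference was 0.084, and after cyclic loess 0.079.

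Genes of mitosis were lower on the compound 1 array as a group. All 25 measured members were lower (24 after each of the 3 scalings, which turned KIF4A), with a median difference of -0.27, and 0 of the 10000 level-matched random lists had a lower median (central 95% from -0.13 to -0.017). The spindle checkpoint kinase TTK was at -0.46, the kinesins KIF20A and KIF2C at -0.38 and -0.36, and the proliferation marker MKI67 at -0.28. Of 26 genes of DNA replication, 21 were lower (20 after each scaling), with a median of -0.15 at percentile 0.60 (-0.081 after quantile normalization and -0.091 after cyclic loess). Among these were the replicative helicase subunits MCM6 (-0.50) and MCM4 (-0.37) and the cell cycle repressor E2F8 (-0.48).

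Targets of the hypoxia-inducible factors were lower as well, in 19 of 23 measured members (17 after each scaling), with a median of -0.17 at percentile 0.19 (-0.10 after quantile normalization and -0.096 after cyclic loess). After DDIT4 the angiogenic growth factor VEGFA was lowest at -0.47, followed by ANKZF1 at -0.44, while STC2 and ANGPTL4 were higher by 0.21 and 0.18. Of 19 listed glycolysis enzymes 9 were measured. Their median was -0.13, at percentile 17.8 (-0.058 after quantile normalization and -0.063 after cyclic loess), with PGK1 at -0.29 and LDHA at -0.21. The 6 measured of 12 regulators of the hypoxia-inducible factors had a median of -0.025, at percentile 62.4 (-0.0021 after quantile normalization). Among them EPAS1, which encodes the HIF-2 alpha subunit, was higher by 0.28.

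Of 22 targets of the amino acid response factor ATF4, 18 were lower (17 after each scaling), with a median of -0.16 at percentile 0.33 (-0.098 after quantile normalization). DDIT4 had the largest difference in this list too (-0.79), and both it and STC2 also belong to the hypoxia targets, so the lists overlap. Other lower members were the serine synthesis enzyme PSAT1 (-0.37) and the tRNA synthetases WARS1 (-0.37) and SARS1 (-0.31), whereas ATF3 was higher by 0.29. The 5 measured metallothioneins, which bind zinc and copper, were all lower, with MT1E at -0.59 and MT1X at -0.49. Their median of -0.21 lay at percentile 2.34, at 2.95 after quantile normalization and 3.58 after cyclic loess, and with no filter the 8 named ones had -0.35 at percentile 0.010.

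**Figure D2:**
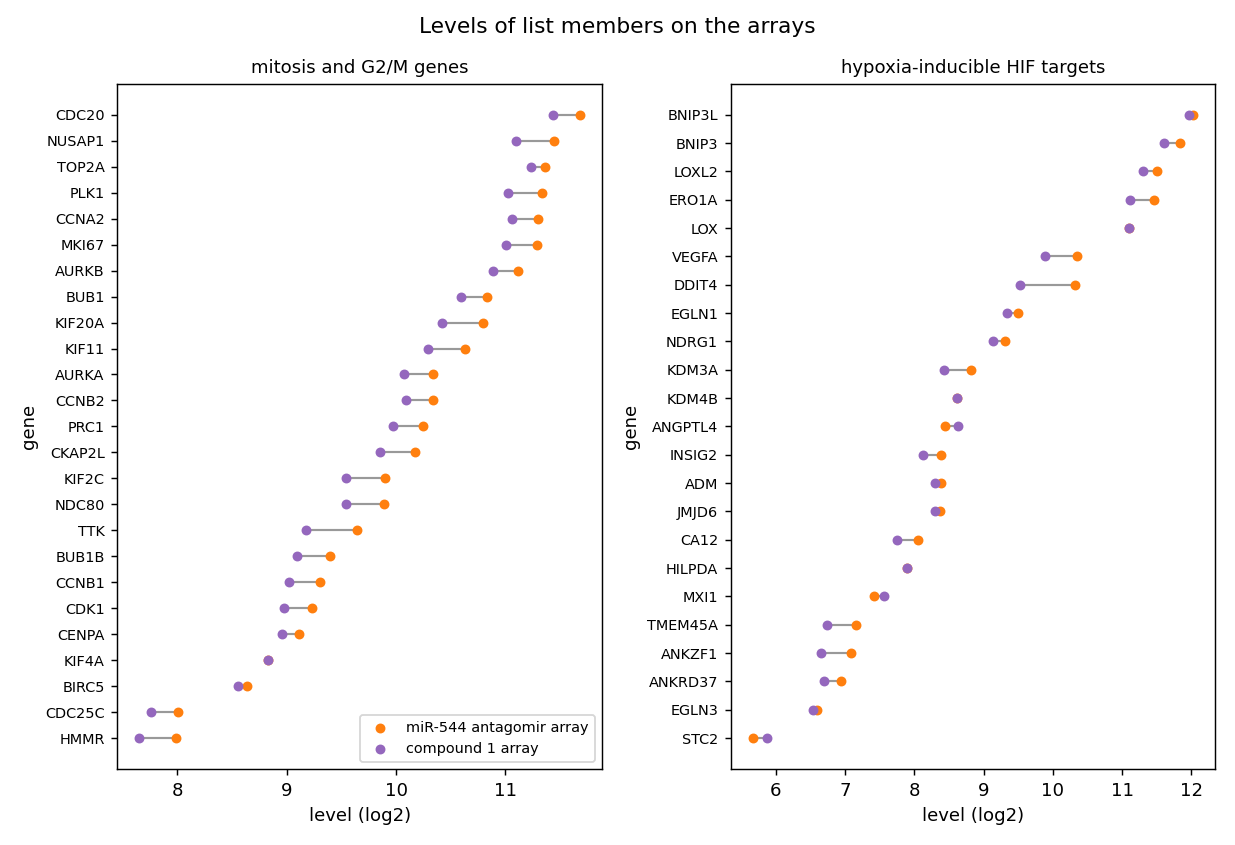
Levels (log2) of the measured members of the mitosis list (25 genes) and of the hypoxia-inducible factor targets (23 genes) on the antagomir array (orange) and the compound 1 array (purple), with a line joining the values of each gene. All 25 mitosis genes lie lower on the compound 1 array, from -0.0038 for KIF4A (which turns after each of the 3 scalings) to -0.46 for TTK, against 19 of 23 hypoxia targets.

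The measured members of the mTOR and ATM lists had medians inside the range of random lists. Of 43 mTOR pathway components 22 were measured. Their median was -0.069, at percentile 38.0 (-0.011 after quantile normalization and -0.0032 after cyclic loess, each with 11 members lower and 11 higher). The mTOR-activating GTPase RHEB was at -0.48 and RRAGC at 0.27. Of 26 genes of ATM signalling and double-strand break repair 15 were measured. Their median was -0.14, at percentile 5.12 (-0.069 after quantile normalization and -0.065 after cyclic loess). Of these, 13 were lower (8 after either of these scalings), among them the checkpoint kinase CHEK2 (-0.42). With entry at the 75th percentile of level, 13 of the 15 ATM list genes remained measured and their percentile was 71.8.

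In total 5 of the 30 lists with a percentile lay at or below percentile 2.5 and 0 beyond the upper bound, where 1.5 would be outside if 5% fell there. The figure of 1.5 holds for independent genes, and members of a list may vary together. Interferon response genes had a median of 0.038 (percentile 92.7; 0.088 after quantile normalization), with ISG15 higher by 0.41, OASL by 0.40 and MX2 by 0.37. With the value after quantile normalization in brackets, chaperones of the endoplasmic reticulum were at 0.0064 (0.053), p53 targets at 0.0090 (0.057), cholesterol synthesis genes at -0.084 (-0.050), heat shock genes at -0.079 (-0.025), ribosomal proteins at -0.077 (-0.0090), oxidative phosphorylation subunits at -0.12 (-0.058), microRNA processing genes at -0.14 (-0.069), RNA polymerase and nucleolar genes at -0.14 (-0.079) and housekeeping genes at -0.14 (-0.058). With entry at the 75th percentile of level, p53 targets (-0.11) and chaperones of the endoplasmic reticulum (-0.017) turned sign, cholesterol synthesis genes were at -0.14 and interferon response genes at 0.013. Medians whose sign turned under a scaling were those of apoptosis regulators (-0.0054), inflammatory genes (-0.0072), NRF2 targets (-0.030), autophagy genes (-0.031), immediate early genes (-0.023), fatty acid synthesis genes (-0.061), epithelial markers (-0.0060), mesenchymal markers (-0.022) and collagen and matrix genes (-0.045). None of the 6 measured members of the collagen and matrix list is a collagen, so they are called matrix genes below. Markers of leukocytes (-0.033) and endothelium (0.057) lay inside the random range. The 4 measured members of the aryl hydrocarbon receptor list (median -0.059) and 3 adipocyte markers (median 0.099) were too few for a percentile. The former list holds the receptor gene AHR itself, at -0.12. Of the histone and erythroid lists 0 members were measured.

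**Figure D3:**
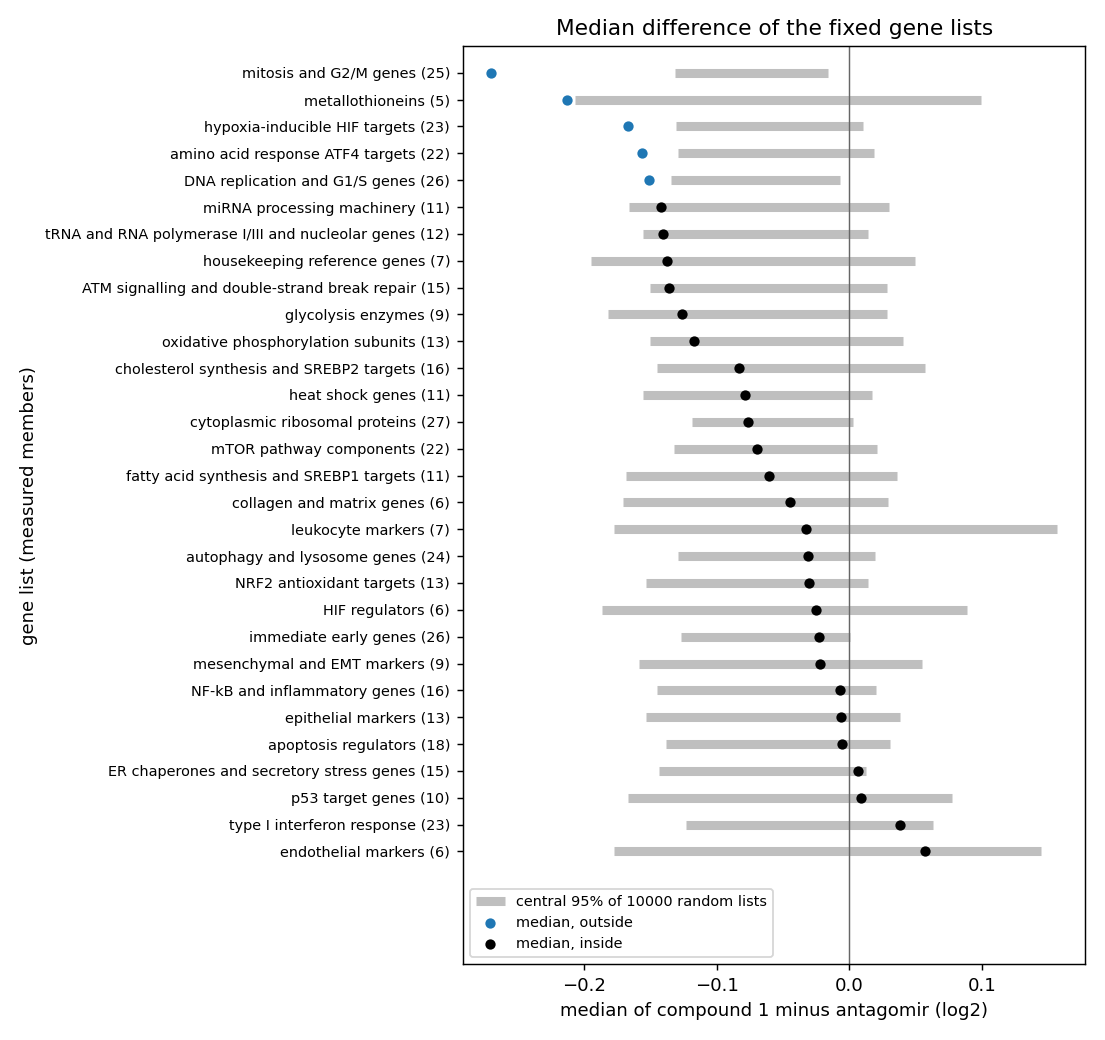
Median difference of each of the 30 gene lists (compound 1 minus antagomir, log2; points), with the number of measured members in brackets and the central 95% of 10000 level-matched random lists (grey bars). The 5 lists in blue lie below the bars, from -0.27 for mitosis to -0.15 for DNA replication.

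No difference between the arrays has a replicate check, so treatment cannot be separated from pool or hybridisation. Where a gene had 2 entering clusters (428 genes), their differences correlated with r = 0.390 across genes and had the same sign in 62.6%, or r = 0.309 and 57.4% without the 52 pairs of identical values. With entry at the 75th percentile of level r was 0.592 (151 genes), and with no filter it was 0.294 (779 genes).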

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

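The protein-coding random background, the list without DDIT4, the omission of identical cluster pairs and the omission of genes with identical values on both arrays were chosen after seeing the data; the others were chosen before the data were examined. No result turned its direction among those outside the random range. Over their alternatives the mitosis median ranged from -0.27 to -0.19 with a percentile of 0.00 in all 11, the hypoxia targets lay at percentiles of 0.010 to 0.71, the ATF4 targets at 0.14 to 0.975 and the replication genes at 0.19 to 0.86. Their medians shrank after quantile normalization and cyclic loess: to -0.19 and -0.20 for mitosis, -0.10 and -0.096 for hypoxia targets, -0.098 and -0.11 for ATF4 targets, and -0.081 and -0.091 for replication. The alternatives are not independent checks. Centring shifts all genes alike and cannot move a percentile. The other filters kept all 25 mitosis genes with the same median, and most genes have 1 cluster. Metallothioneins moved inside the random range with a median of -0.14 after quantile normalization (-0.1445) and cyclic loess (-0.1403), while with no filter the median of 8 members was -0.35 at percentile 0.010. Without the 122 genes of identical values, 5 lists were outside as before. Of single named genes, 241 values stayed within 1 robust SD of genes at their level and 1 did not, EGR1 at 0.46 with the cluster of median difference. Many of these values could not change. A filter left the value of a gene that stayed measured as it was, and among these genes the cluster choice could alter only EGR1. For the other named genes the count therefore tests the scalings only. The number of lists outside was 4 or 5 in each setting run on all lists; with entry at the 75th percentile 26 of the 30 lists had enough members, and metallothioneins did not.

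Quantile normalization and cyclic loess moved the median of all genes from -0.035 to 0.0048 and -0.0046, and several list medians by more. In the deposited values the difference ran from a median of 0.094 in the lowest decile of clusters to -0.070 in the highest. Cyclic loess removes such a trend. How far it accounts for the move of each list was not tested. After quantile normalization and after cyclic loess respectively, the medians were -0.058 and -0.063 for glycolysis, -0.011 and -0.0032 for mTOR components, -0.069 and -0.065 for ATM signalling, 0.058 and 0.055 for apoptosis, 0.053 and 0.050 for chaperones of the endoplasmic reticulum, -0.025 and -0.011 for heat shock, 0.034 and 0.030 for NRF2 targets, -0.069 and -0.075 for microRNA processing, 0.021 and 0.015 for autophagy, 0.018 and 0.0085 for matrix genes, -0.058 and -0.066 for oxidative phosphorylation, -0.0090 and -0.020 for ribosomal proteins, 0.057 and 0.050 for immediate early genes, -0.079 and -0.089 for RNA polymerase and nucleolar genes, and -0.058 and -0.072 for housekeeping genes. In the same order, interferon genes were at 0.088 and 0.075, fatty acid synthesis at 0.0058 and -0.010, epithelial markers at 0.050 and 0.032 and mesenchymal markers at 0.036 and 0.028; for these 4 the move was within 1 SD of random lists after cyclic loess only.

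The filter on low levels decided the counts. With no filter 44 genes passed 2-fold (29 higher, 15 lower, with 3 and 3 of them protein-coding). Mesenchymal markers were then at 0.034, matrix genes at 0.010, the cluster pairs correlated with r = 0.294, and 10 of the 30 named genes were shared. With entry at the 75th percentile 1 gene passed (1 higher, 0 lower), the pairs correlated with r = 0.592, 9 named genes were shared, and the medians were -0.044 for ATM signalling, -0.11 for p53 targets and -0.14 for cholesterol synthesis. With both arrays at or above the entry level 2 genes passed (1 higher, 1 lower) and 14 named genes were shared. At 1.5-fold 94 genes passed (34 higher, 60 lower) and at 3-fold 1 (1 higher, 0 lower). No paired analysis was possible because each treatment has 1 array. The array controls, the seed matches, the suffix choice and the floor before the logarithm were not run. The spread of differences was widest at low signal, with a robust SD of 0.28 in the lowest of 20 level bins and 0.10 in the highest.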

Other observations

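The families and the tests on them in this part were chosen after the differences had been seen, as were the tests without DDIT4 and among protein-coding genes. Several small non-coding RNA genes were higher on the compound 1 array. The vault RNA genes VTRNA1-1 (6.35, against 5.37 and so under the entry level on the antagomir array) and VTRNA1-3 (7.38 against 6.88) were higher, VTRNA1-2 was under the entry level on both arrays, and VTRNA2-1 was lower, at -0.22; these directions held under the 3 scalings. The 18 small Cajal body RNA genes had a median of 0.10, and 0.12 to 0.14 under the scalings.

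In a scan of 137 symbol prefixes with 10 or more genes, 7 lay at or below percentile 2.5 of 2000 level-matched random lists (CEP, DDX, MCM, MRPL, RBM, VPS and ZNF) and 9 beyond the upper bound (ABHD, AQP, KRTAP, MIR, SCARNA, SH, SLC, STX and SYT), where 6.85 would be outside if 5% of lists of independent genes fell there. Families taken from these extremes are described here without a test, since they were picked for their differences. Among protein-coding genes 58.9% were lower, a share that is not matched on level. Counting protein-coding genes only, 42 of 48 MRPL genes of the mitochondrial large ribosomal subunit were lower on the compound 1 array (median -0.15). So were 29 of 32 centrosomal CEP genes (-0.14), 25 of 30 RNA-binding motif genes (-0.14) and 254 of 380 zinc finger genes named ZNF (-0.094). The MRPS genes of the small subunit (17 of 25 lower, -0.031) lay inside the level-matched range of -0.13 to 0.0035, at percentile 82.2. After quantile normalization and cyclic loess respectively, 37 and 37 MRPL genes were lower (-0.088 and -0.091), 26 and 28 CEP genes (-0.093 and -0.10), 20 and 22 RNA-binding motif genes (-0.11 and -0.13) and 232 and 240 ZNF genes (-0.057 and -0.069), while the MRPS genes turned to medians of 0.039 and 0.019 with 11 lower in each. Among the unnamed clusters, 1530 entering clusters numbered below the first named one had an SD of 0.57, with 26 higher and 112 lower past 2-fold.

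The lower mitosis genes could follow the trend of the difference with signal level, which ran from a median of 0.094 in the lowest decile of clusters to -0.070 in the highest. After cyclic loess, which removes that trend, their percentile was still 0.00. Among 6054 protein-coding genes with entry at the 75th percentile of level it was 0.00 too. Both reruns matched random lists on level, as the main setting did, so they add little to it. In the rerun on protein-coding genes all 25 members remained, and their median of -0.27 lay below the random range of -0.13 to -0.016. The mitosis genes were thus lower than well expressed genes at their own level, so a drop shared by all such genes would not account for the whole difference. A difference between the pools or hybridisations unrelated to treatment stays open, because there is 1 array per treatment. An effect of the treatment also stays open, untested.

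The lower hypoxia targets may likewise follow the level trend. Their percentile among level-matched lists was 0.19 before and 0.71 after cyclic loess, so they lay below genes at their own level. As for mitosis, the loess value adds little to the matching. Without DDIT4 the percentile was 0.16, but a median of 23 members could hardly rest on 1 of them. Pool or hybridisation stays open here as well, with 1 array per treatment, as does an effect of the treatment, untested.

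The 385 measured microRNA genes had a median of 0.082, with 131 lower on the compound 1 array, and 32 keratin-associated protein genes had 0.11, with 7 lower. After cyclic loess the medians were 0.091 and 0.15, so neither shrank when the trend with level was removed. A slightly higher background on the compound 1 array could raise both families. Such a background was tested on a list of tissue-restricted genes, written before its values but after those of the keratin-associated genes were seen, in place of a first choice of receptor and defensin genes that had too few named members. With no filter, its 41 measured genes had a median of 0.062 and lay at percentile 66.0. The random lists were matched on level, so a rise shared by all genes of low signal could not show. The test therefore decides neither way. A treatment effect on small RNA precursors was not tested.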
